A study of Caenorhabditis elegans with 6 samples.

How the data were processed

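Messenger RNA was measured in descendants of the QR neuroblast of Caenorhabditis elegans, taken from first-stage larvae that had been fed for 7 hours and collected in pools of 2000 cells. Control larvae carried the mab-5 deletion allele gk670 with the integrated transgenes huIs166 and ayIs9. ΔN-BAR-1 larvae carried the same alleles and the additional transgene huIs179, and the series describes them as producing an N-terminally truncated form of the β-catenin BAR-1 in the Q lineage. Each group had 3 libraries, with replicate numbers given in the sample titles. Nothing in the labels says whether these came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

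Per the labels' protocols, reverse transcription, barcoding and in vitro transcription followed CEL-seq, and the sequencing libraries followed CEL-seq2, so that 3′ ends of transcripts were counted. The authors deposited estimated counts of transcripts per gene that had not been normalised between libraries. The aligner, annotation, genome build and counting steps are not given in the sources used here. The deposited values themselves showed how they had been made. Inverting the usual correction for molecular identifiers that meet by chance, with 256 possible identifiers, gave whole numbers of distinct identifiers, within a tolerance of 0.02, for at least 99.9% of the values above 0 in each library. A gene that had used every identifier had been set to 255.5 identifiers, an estimate of 1597 transcripts. The column of ΔN-BAR-1 replicate 3 had been computed with a rescaled form of the correction, rounded to 2 decimals, and its saturated genes had been set to 3182. Once every identifier was used, the number of identifiers no longer gave the number of transcripts. The values at these ceilings were therefore set, and may lie above or below the true abundance. No column was left unused.

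The estimated counts were rounded to whole numbers. Library totals were then 154785, 254362 and 68431 for control replicates 1 to 3 and 190078, 222664 and 237644 for ΔN-BAR-1 replicates 1 to 3, with 6223 to 8110 genes detected. A single count corresponded to between 4.11 and 16.5 CPM, the coarsest being in control replicate 3. Gene names were used as deposited. Of 14700 names, 13224 were in the gene symbol table used here, 1211 matched a RefSeq locus tag and 265 matched neither. No coordinates are given, since no build was named.

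Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, filterByExpr with the group (min.count 10, min.total.count 15) and the quasi-likelihood F test with robust empirical Bayes (two-sided), on all 6 libraries with the group as the only term. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistics, and CPM (counts scaled to library size) use the TMM-scaled library sizes. The common biological coefficient of variation was 0.321. Same-group libraries differed by more than counting noise (chi-square over degrees of freedom 2.98 to 10.8), which gives no sign of a library deposited more than once but does not show whether they are biological or technical replicates.

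Gene lists (20 of them, chosen for Wnt signalling, the Q lineage and other cell types of the larva) were tested where at least 5 members passed the filter, with camera of limma 3.58.1 at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over those lists. Camera with an estimated correlation and fry were alternatives. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the smallest adjusted p per direction among called genes whose groups did not overlap (where fewer than 5 passed, the 5 with the smallest p), together with bar-1, mab-5, egl-17, unc-54, mig-1, lin-39 and up to 4 members per list with the smallest p. Other genes named below were chosen after their values were seen.

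The edgeR steps were tested on simulated counts for this comparison, with 3210 genes passing the filter. They recovered 15.8% of 95 genes changed 2-fold and 76.0% of 96 genes changed 4-fold, with 10 false calls, so changes near 2-fold were mostly below what 3 against 3 libraries resolve. The list test found the 1 raised list and called 0 of 19 unchanged lists. The simulated genes varied independently of each other, whereas the estimated correlation in the real lists reached 0.64 (ribosomal) and 0.73 (hypodermis and seam). The simulation therefore does not show how often the list test makes false calls on these data.

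Alternatives fixed beforehand were DESeq2 size factors, upper quartile scaling, no low-count filter (minimum total 1), a stricter filter (min.count 30), DESeq2 1.42.0, limma-voom, non-robust empirical Bayes, the replicate number as a block, leaving out each library, a threshold of 0.1 and a test against a 1.5-fold change. Added after seeing the data were the recovered identifiers, 1 form of the identifier correction for all libraries, thinning to the shallowest library (repeated with 20 further random draws), and leaving out replicate 3 of both groups.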

Results

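The series asked which genes respond to canonical Wnt signalling in QR neuroblast descendants, by comparing 3 control pools with 3 pools carrying activated BAR-1. BAR-1 is the β-catenin that acts with the TCF factor POP-1 in this pathway, and both groups lacked mab-5 function, a Hox gene of Q cell migration. Library totals ranged from 68431 to 254362 estimated transcripts. The transgene could not be followed by its own counts. Transcripts of bar-1 numbered 1, 4 and 0 in the control libraries and 3, 4 and 8 in the ΔN-BAR-1 libraries, below the filter, and 3′ counting would show the transgene only if it carried the bar-1 3′ end. The 3′ counts of mab-5 likewise need not be affected by the deletion; they were 380 ± 49.9 counts scaled to library size (CPM) in control and 294 ± 107 in ΔN-BAR-1 libraries (SD, n = 3 each; log2 fold change −0.38, edgeR quasi-likelihood adjusted p = 0.783). The fibroblast growth factor gene egl-17, whose reporter ayIs9 is known to be, had a log2 fold change of −0.93 ± 0.56 (SE; edgeR adjusted p = 0.592). The muscle myosin gene unc-54 had one of 0.76 ± 0.53 (edgeR adjusted p = 0.692) and had reached the ceiling of 3182 in ΔN-BAR-1 replicate 3. Its value rested on single libraries and on the identifier correction: it was −0.07 without ΔN-BAR-1 replicate 3, −0.59 with distinct identifiers and 0.205 with a common correction, and passed the test at 1.22 (edgeR adjusted p = 0.0145) without ΔN-BAR-1 replicate 1.

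With ΔN-BAR-1, 5 of 7 tested touch neuron genes and 4 of 29 tested neuronal and synaptic genes rose. The neuropeptide gene nlp-35 was higher by 4.23 ± 0.58 on the log2 scale (SE), from 17.5 ± 13.7 to 274 ± 113 CPM (SD, n = 3 each). The ETS factor gene ast-1 rose by 3.26 ± 0.46, the SLT-1 coreceptor gene eva-1 by 2.86 ± 0.41 and the LIM homeobox gene mec-3, a determinant of touch neurons, by 2.71 ± 0.41, from 60.1 ± 12.63 to 417 ± 146 CPM. The α-tubulin gene mec-12 rose by 1.94 ± 0.33. The BarH-type homeobox gene ceh-31 rose by 3.52 ± 0.60 and the Distal-less homologue ceh-43 by 2.21 ± 0.39. C02B10.3 (3.54), ZK265.7 (3.61), T03G6.3 (3.08), H11E01.3 (3.29) and Y44A6D.2 (1.95), whose symbol is now tpan-1, completed the 12 genes with the smallest adjusted p, which ran from 0.000513 to 0.00374 (edgeR quasi-likelihood, Benjamini-Hochberg). Control replicates 1 to 3 held 1, 3 and 2 transcripts of nlp-35, 2, 7 and 0 of ceh-31, and 2, 3 and 3 of H11E01.3. The sizes of these changes are therefore uncertain.

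Among 3447 genes tested, 57 changed, of which 54 were higher and 3 lower, and in each of the 57 the 3 libraries of one group lay apart from those of the other, as 17.4% of all tested genes did against 10% by chance. At an unadjusted p below 0.05 there were 283 higher and 118 lower genes. The 3 lower genes were the replication helicase gene mcm-7 (log2 fold change −1.53 ± 0.32, from 999.9 ± 252 to 341 ± 55.2 CPM), the low-density lipoprotein receptor-related gene lrp-2 (−1.41 ± 0.31) and the kinetochore gene zwl-1 (−2.04 ± 0.47), with edgeR adjusted p of 0.0136, 0.0182 and 0.0241. Each of these 3 calls ended without control replicate 1 (edgeR adjusted p = 0.0823, 0.187 and 0.300); mcm-7 was also lost without control replicate 3, zwl-1 without control replicate 2, and lrp-2 without control replicate 2 or 3 or ΔN-BAR-1 replicate 2. The proneural gene lin-32 (−1.24, edgeR adjusted p = 0.0685) and the checkpoint kinase gene chk-1 (−1.54, 0.0718) were next in order. The count of changed genes was 16, 21 and 26 without control replicate 1, 2 or 3, and 121 and 86 without ΔN-BAR-1 replicate 1 or 3. Of the 57 genes, 10 kept their call whichever single library was left out (nlp-35, ast-1, eva-1, mec-1, mec-3, mec-12, ceh-31, C02B10.3, ZK265.7 and T03G6.3), and 42 lost it without control replicate 1. The count was 31 with counts thinned to the shallowest library, and 9 with limma-voom.

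The Wnt receptor gene mig-1 rose, from 126 ± 24.8 to 366 ± 114 CPM (SD, n = 3 each; log2 fold change 1.52 ± 0.38, edgeR adjusted p = 0.0415). It was called in 8 of 18 alternatives, with log2 fold changes between 1.32 and 1.73, and leaving out any control library ended the call (adjusted p 0.145 to 0.300), as did leaving out ΔN-BAR-1 replicate 2 (0.0959). It was the only changed member among 21 tested Wnt pathway components, both over all genes and adjusted over the list alone, and the median of that list was −0.003 (camera adjusted p = 0.753). The β-catenin gene wrm-1 stood at 0.93 ± 0.38, the Dishevelled gene dsh-2 at −0.69 ± 0.33 and pop-1 at 0.62 ± 0.35. Among 6 tested genes reported as BAR-1 or POP-1 targets, mig-1 was again the only change, both over all genes and adjusted over the list alone, with the Hox gene lin-39 at 0.25 ± 0.34 and the GATA factor gene egl-18 at 0.42 ± 0.33 (camera adjusted p = 0.224). The list of Hox genes and cofactors had 3 tested members and 0 changes, 0 also at an unadjusted p below 0.05 and by DESeq2 and limma-voom, with unc-62 at −0.22 ± 0.30.

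Of 7 tested touch neuron genes, 5 rose, both over all genes and adjusted over the list alone. These were mec-1, which encodes an extracellular matrix protein (4.11 ± 0.74), mec-3, mec-18 (2.63 ± 0.50), mec-12 and the β-tubulin gene mec-7 (1.45 ± 0.32), while mec-8 and the POU factor gene unc-86 stood at −0.19 and −0.16. The control libraries together held 5 transcripts of mec-1, so the size of its change is uncertain. The calls of mec-18 and mec-7 ended without control replicate 1 or 2, and that of mec-7 also without control replicate 3 or ΔN-BAR-1 replicate 2. The list's median was 1.94 (camera adjusted p = 4.35e-06, and adjusted p = 0.0851 with an estimated correlation). A list of oxygen-sensing neuron genes was chosen for AQR, which the QR lineage makes, though not all of its members are particular to AQR. Of these, 0 of 7 tested passed over all genes, and 5 did adjusted over the list alone, the same number as at an unadjusted p below 0.05 (DESeq2 and limma-voom called 0). Those 5 were guanylate cyclase genes, among them gcy-33 (2.12 ± 0.55), gcy-32 (1.38 ± 0.37), gcy-34 (1.56 ± 0.52) and gcy-37 (1.05 ± 0.36). The cyclase gene gcy-36 stood at 0.40 ± 0.31 (edgeR adjusted p = 0.721) and ahr-1 at 0.49. The list's median was 1.05 (camera adjusted p = 1.65e-05, and adjusted p = 0.0723 with an estimated correlation). The fry test, which asks whether the genes of a list move one way on balance, gave an adjusted p of 0.0131 for each of these lists.

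Neuronal and synaptic genes shifted upward, with 27 of 29 tested members above 0 and a median of 1.13 (camera adjusted p = 2.18e-09, and adjusted p = 0.0851 with an estimated correlation; fry adjusted p = 0.0523). Over all genes 4 rose: the SNAP-25 gene ric-4 (2.04 ± 0.37), the kinesin gene unc-104 (2.74 ± 0.56), the vesicle GTPase gene rab-3 (1.97 ± 0.42) and the calcium channel gene egl-19 (3.12 ± 0.66). Without control replicate 1 all 4 calls ended (edgeR adjusted p = 0.106, 0.106, 0.183 and 0.105), as did that of unc-104 without control replicate 2 and the other 3 without control replicate 3; the egl-19 log2 fold change ran from 2.54 to 4.82 over its alternatives. ΔN-BAR-1 replicate 1 had the highest sum over this list, 15350 CPM against 12739 and 14591 in replicates 2 and 3, and without it the median was 0.95. Adjusted over the list alone, 12 were higher and 1 lower, the lower one being the β-tubulin gene tbb-1 (−0.90).

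**Figure D1:**
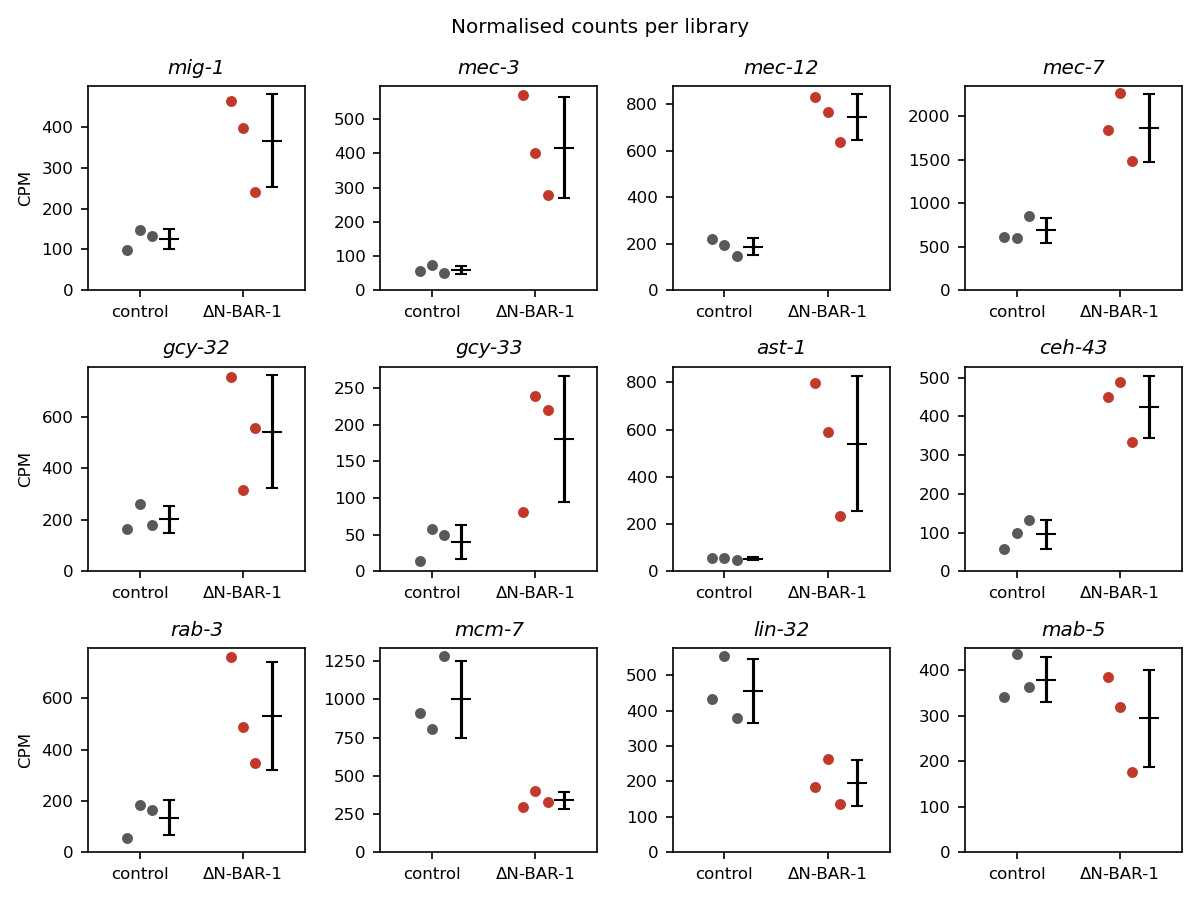
Normalised CPM of 12 genes in the 3 control and 3 ΔN-BAR-1 libraries (points), with the mean and SD of each group (bars to the right of the points). In mec-3 the control mean was 60.1 and the ΔN-BAR-1 mean 417, whereas mcm-7 went from 999.9 to 341 and mab-5 overlapped between groups.

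Cell cycle and DNA replication genes shifted downward, with 41 of 48 tested members below 0 and a median of −0.63 (camera adjusted p = 3.31e-11, and adjusted p = 0.0649 with an estimated correlation; fry adjusted p = 0.0102). Only mcm-7 passed for itself, over all genes and adjusted over the list alone. The kinesin gene klp-18 stood at −1.69 ± 0.48 and the helicase genes mcm-5 and mcm-4 at −1.08 ± 0.35 and −0.93 ± 0.31. The summed expression of the list was 19742 ± 1601 CPM in control and 13266 ± 881 in ΔN-BAR-1 libraries (SD, n = 3 each).

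Genes of Q lineage fate went both ways. Of 14 tested, mec-3 rose over all genes, and adjusted over the list alone mec-3, the proneural gene hlh-14 (1.78 ± 0.53) and the zinc finger gene sem-4 (1.11 ± 0.33) were higher and lin-32 lower. The list's median was −0.29 and its mean 0.09, and camera gave a downward direction at an adjusted p of 0.783. Among 31 tested migration and guidance genes, 0 changed over all genes and 0 adjusted over the list alone, with max-2 at 0.99 ± 0.34, unc-44 at 0.97 ± 0.36, ptp-3 at 1.04 ± 0.40 and efn-4 at −1.19 ± 0.45 (camera adjusted p = 0.224). At an unadjusted p below 0.05 the migration list had 6 genes by edgeR. Programmed cell death genes, 9 tested, also gave 0 over all genes and 0 adjusted over the list alone, with the caspase activator gene ced-4 at −0.68 ± 0.42 (camera adjusted p = 0.224) and 0 genes at an unadjusted p below 0.05. DESeq2 and limma-voom called 0 genes of either list.

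Cytosolic ribosomal protein genes, 72 tested, had a median of −0.27 with 0 single genes changed, over all genes or adjusted over the list alone (camera adjusted p = 4.1e-06, and adjusted p = 0.690 with an estimated correlation). ΔN-BAR-1 replicate 1 stood apart, with 72846 CPM from these genes against 131098 to 148470 in the other libraries, and without it the median was −0.01 (camera adjusted p = 0.639). Nuclear genes of oxidative phosphorylation, 25 tested, gave a median of −0.27 and 0 changed genes by either adjustment (camera adjusted p = 0.00946, and adjusted p = 0.690 with an estimated correlation); without ΔN-BAR-1 replicate 1 the median was −0.07 (camera adjusted p = 0.371), and after thinning the adjusted p was 0.0512. At an unadjusted p below 0.05 edgeR gave 2 ribosomal and 1 oxidative phosphorylation gene, and DESeq2 and limma-voom called 0. The number of preset-correlation camera calls is not specific to the real grouping, since 5 of the 10 ways to split the 6 libraries into 3 and 3 called at least as many lists. The ribosomal list was called in 10 of them, the oxidative phosphorylation, cell cycle and neuronal lists in 6 each, and the touch neuron and oxygen-sensing lists in 3 each. For the touch neuron, oxygen-sensing, cell cycle and neuronal lists the real grouping gave the smallest camera p, but 10 splits are too few to judge by.

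Markers of other larval cells showed 0 changes over all genes. Body wall muscle markers (18 tested) had a median of −0.05, a mean of −0.20 and an upward camera direction (adjusted p = 0.783), with unc-97 at 0.87 ± 0.36 and mlc-2 at −1.02 ± 0.50. Hypodermis and seam markers (5 tested) had a median of −0.06 (adjusted p = 0.305). ΔN-BAR-1 replicate 1 was low in both lists, with 8534 CPM of muscle markers against 16231 and 22851 in replicates 2 and 3, and 397 CPM of hypodermis and seam markers against 884 and 1244. Much of the muscle sums was unc-54 alone, with 2272, 7218 and 15580 CPM in these libraries, the last at its set ceiling. By the mean log2 CPM of the tested muscle markers relative to all libraries, replicates 1 to 3 stood at −0.76, −0.06 and 0.42, and control replicate 2 at −0.61. Heat shock and stress genes (22 tested) had a median of −0.19 (adjusted p = 0.224), with the heat shock factor gene hsf-1 at 1.23 ± 0.36. Adjusted over the list alone, these 3 lists gave 0 changes; at an unadjusted p below 0.05 edgeR gave 1, 0 and 2 genes, and DESeq2 and limma-voom called 0. Lists with fewer than 5 tested members were not tested as lists: pharynx (tbx-2 at −1.14 ± 0.42), intestine (erm-1 at −0.56 ± 0.33) and glia (lin-26 at 0.30 ± 0.38) had 1 each, coelomocyte and excretory cell 4 (exc-9 at −1.19 ± 0.40), and germline 0. Adjusted over the list alone, tbx-2 and exc-9 were lower (adjusted p = 0.0132 and 0.0304 by edgeR), the first in a list of 1 tested gene.

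**Figure D2:**
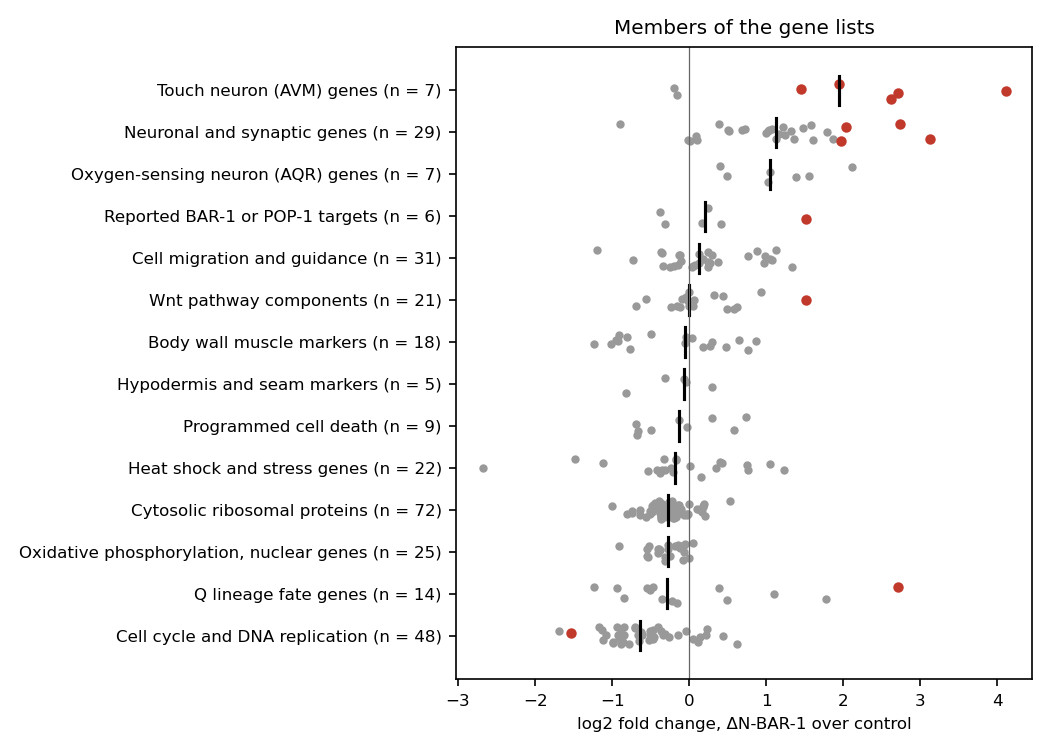
Log2 fold change (ΔN-BAR-1 over control) of each tested member of the 14 lists with at least 5 tested members, with n the number of members. Red points passed the adjusted p of 0.05 over all genes, and black bars mark medians, which run from 1.94 for touch neuron genes to −0.63 for cell cycle genes.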

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

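The 57 changed genes kept their sign under every alternative that tested them; 33 were tested with the stricter filter and 35 after thinning. Thinning, the 2 treatments of the identifiers and the omission of replicate 3 from both groups were chosen after the data were seen. Genes changed (higher, lower) numbered 101 (95, 6) without a filter, 35 (33, 2) with the stricter filter, 9 (9, 0) with limma-voom, 31 (30, 1) after thinning, 17 (17, 0) without replicate 3 of both groups, 113 (99, 14) at a threshold of 0.1 and 25 (25, 0) against a 1.5-fold change. Fewer genes were tested with the stricter filter (1414) and after thinning (1503); for the others the cause was not tested. Leaving out single libraries gave 16 to 121 changed genes, 16 to 108 higher and 0 to 13 lower. Of the 57, 15, 19 and 25 were shared without control replicate 1, 2 or 3, and 51, 42 and 51 without ΔN-BAR-1 replicate 1, 2 or 3. DESeq2 size factors (57), upper quartile scaling (39), DESeq2 (60, with 402 adjusted p not given), the non-robust fit (49), distinct identifiers (58) and a common identifier correction (58) stayed within 1.5 times the count. With the replicate number as a block, 19 genes changed (18 higher, 1 lower), 18 of them shared. After each gene's group mean was subtracted, same-numbered libraries correlated at −0.15, −0.08 and −0.03, and differently numbered ones at −0.06 to 0.11. This gave no sign that the numbers pair the samples, but with 3 libraries a group it cannot exclude a shared day or culture. Lists called numbered 4 to 8 without a single library, 5 after thinning and 8 without replicate 3 of both groups, but 0 with an estimated correlation (4 at an unadjusted p below 0.05) and 3 by fry. Of 1314 values of named genes under alternatives, 1229 kept their side of the threshold, 65 lost a call, 20 gained one, and 0 called values changed sign. Of 54 named genes that were not called, 13 were called in at least 1 alternative, and 8 changed sign in at least 1 (exc-4, grd-10, hsp-16.2, lin-39, mup-4, unc-54, vha-1 and vha-8). Over 20 further thinnings, 20 to 42 genes changed. In control replicate 3, the shallowest library, 3 counts equal 49.4 CPM, which limits what can be said of genes below that level.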

Other observations

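Several changed genes lay outside the lists. The stomatin-like gene unc-24 rose by 2.96 ± 0.53 on the log2 scale, the synapsin gene snn-1 by 2.40 ± 0.47, the L1CAM-type adhesion gene lad-2 by 2.32 ± 0.50, the potassium channel gene twk-7 by 2.51 ± 0.54 and the ryanodine receptor gene unc-68, best known from body wall muscle, by 3.34 ± 0.67 (edgeR quasi-likelihood adjusted p 0.00455 to 0.0167). The FMRFamide-like peptide genes flp-5 and flp-12 rose by 1.64 and 2.86, and the FOXO gene daf-16 by 2.31. These genes were picked after their values were seen, and each lost its call when some single control library was left out (unc-24 and snn-1 only without control replicate 2). All control libraries together held 8 transcripts each of unc-24 and unc-68 and 5 of flp-12, so the sizes of those changes are uncertain. The transmitter genes looked at were near the floor: the 3 control libraries held 7 transcripts of the GABA gene unc-25 and 5 of the acetylcholine transporter gene unc-17, against 0 and 0 in the ΔN-BAR-1 libraries, and the glutamate transporter gene eat-4 had 2 against 13.

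Grouping genes by the root of their name, which was done after the data were seen, gave 83 families with at least 5 tested members. Of these, 9 passed camera at the preset correlation (mec, mcm, unc, rpl, gcy, ceh, rps, npp and col) and 0 with an estimated correlation. Nucleoporin genes (npp) had 18 of 22 members below 0 and a median of −0.41, with npp-12 at −1.17 (edgeR adjusted p = 0.123), and 7 homeobox genes named ceh had a median of 0.81, of which ceh-31 and ceh-43 rose. Collagen genes (col) had 11 of 13 members below 0 and a median of −0.66. For npp, ceh and col the camera adjusted p was 0.0107, 0.00179 and 0.0206, and adjusted p = 0.611, 0.893 and 0.893 with an estimated correlation. Without ΔN-BAR-1 replicate 1 the medians of ceh and col were 0.40 and −0.13, and that of npp −0.45.

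Of the tests that follow, those chosen after their result was seen are the touch list without ΔN-BAR-1 replicate 3, all tests of the 3 neuronal lists together, both tests of touch neurons from other lineages, the depth of ΔN-BAR-1 replicate 3, the ratio of F44E5.4 to F44E5.5, and the muscle and whole-cause tests of far-1. The real grouping called 57 genes and each of the other 9 splits of the libraries 0 by edgeR (56 to 178 at an unadjusted p below 0.05, against 401), so that 1 of 10 splits gave as many; for lists it was 5 of 10, with 6 in the real grouping and 8 as the highest other. The 10 splits are too few for a share under 0.05. Bootstrap bounds in these tests came from resampling the genes of a list, which may move together. They leave out the spread between libraries and so describe these 6 libraries only.

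The neuronal list shifted upward and the cell cycle list downward with ΔN-BAR-1, with 4 of 29 and 1 of 48 genes passing over all genes and both list calls lost with an estimated correlation (adjusted p = 0.0851 and 0.0649). Without ΔN-BAR-1 replicate 3, whose identifiers were corrected differently, the cell cycle median was −0.617 (bootstrap bound nearest 0, −0.363) and that of the 3 neuronal lists together 1.005 (lower bound 0.741, against 1.163 with all libraries), which argues against that library as the source; thinning, which argues against depth for the cell cycle genes, left a median of −0.677 (bound −0.415). The touch list alone stood at 2.01 and, thinned, at 1.486, but with so few genes its lower bounds were −0.076 and −0.367. For the 3 neuronal lists, depth as the whole cause is argued against for the genes still tested. Their lower bound stayed above 0 in 20 of 20 further thinnings (lowest 0.345). A part for depth stays open. The first thinning left a median of 1 with a lower bound of 0.345, under the chosen limit of 50% of 1.163. The further draws tested 22 to 27 genes, against 7 touch, 7 oxygen-sensing and 29 neuronal genes with all counts. Medians before and after thinning are thus of unlike sets of genes, and their difference does not measure a part for depth. Touch neurons of other lineages in the pools would not raise the guanylate cyclase genes, whose median had a lower bound of 0.708. That rise is itself uncertain, since 0 of 7 tested genes of their list passed over all genes. The list's call was also lost with an estimated correlation (camera adjusted p = 0.0723). For the touch genes such neurons stay open, with 48 transcripts of mec-4, mec-10 and mec-17 against 12 in control, not scaled to library depth. Of these, mec-17 gave 35 and 12, with 20 in ΔN-BAR-1 replicate 2, and its CPM overlapped between groups. The counts of mec-4 and mec-10 were 6 and 7 against 0 and 0. QR descendants further along their lineage may give both shifts; the test set beforehand found the most neuronal library to be the least proliferative in 0 of 2 groups, which was the outcome named as speaking against it, but with 3 libraries a group chance alone often gives that, so it and a direct response to BAR-1 cannot be told apart.

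In ΔN-BAR-1 replicate 3 the heat shock genes F44E5.4 and F44E5.5 had 3182 and 16 transcripts, and hsp-16.1 and hsp-16.11 had 0 and 0. Low depth is argued against, since 4 of the other 5 libraries had lower totals. The F44E5.4 to F44E5.5 ratio was 198.9 there and 0.92 to 1.3 elsewhere, and the sum of the pair was not low. Both values rest on the set ceiling, so their sizes are not known. Reads of near-identical copies may have been assigned differently in that library. The test set beforehand did not show this: 0 genes with at least 20 transcripts in each other library were at 0, as in every other library. That limit had left out hsp-16.1 and hsp-16.11, with 4 and 7 transcripts in ΔN-BAR-1 replicate 1, which was noticed only afterwards, so for them the explanation stays open.

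The fatty acid and retinol binding gene far-1 rose by 2.39 ± 0.45 (edgeR adjusted p = 0.00933), at the ceilings of 1597 in ΔN-BAR-1 replicate 2 and 3182 in replicate 3. With 1 form of the identifier correction for all libraries the log2 fold change was 1.92 ± 0.39 (edgeR adjusted p = 0.0110), so the higher ceiling of replicate 3 added to it. At the ceilings the size of the change is not known. The call ended without control replicate 1 or 2 (edgeR adjusted p = 0.133 and 0.0838), and on distinct identifiers, which saturate, the log2 fold change was 0.12. More muscle RNA could raise far-1 only with other muscle genes, whose median had an upper bound of 0.289 over resampled genes. The sum of that list ran from 8534 to 22851 CPM between libraries, with unc-54 alone from 2272 to 15580, a spread which this bound leaves out. Within each group far-1 ranked the libraries as the list's mean log2 CPM did. Far-1 had 1285, 1213 and 3129 CPM in control and 5479, 8118 and 15580 in ΔN-BAR-1 replicates 1 to 3. The list's means, relative to all libraries, were 0.12, −0.61 and 0.88, and −0.76, −0.06 and 0.42. A part for muscle RNA therefore stays open. Without ΔN-BAR-1 replicate 3 far-1 stood at 1.848 ± 0.43, above the limit of 1 set beforehand by more than its SE. Less 2 SE the value was 0.989, just under that limit. It also rests in part on the set ceiling of ΔN-BAR-1 replicate 2, which the SE leaves out. Since 0.989 is above 0, this argues against the processing of replicate 3 as the whole cause, though that processing added to the size of the change. A response of far-1 to BAR-1 stays open.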
